A study of Mus musculus with 2 samples.

How the data were processed

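Single-cell RNA sequencing libraries were made from liver non-parenchymal cells of 5-month-old male mice on standard chow, per the labels' protocols. Livers were digested with collagenase, and the suspensions were captured with 10x Genomics v3 chemistry and sequenced on a NextSeq 500. There are 2 libraries, 1 per group. Hep-ADKTg mice overexpress adenosine kinase (Adk), which phosphorylates adenosine to AMP, in hepatocytes from the albumin promoter, and Hep-ADKWT mice are their controls. The labels do not say whether a library came from 1 mouse or from pooled mice.

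The deposited matrices hold raw UMI counts, whole numbers per gene and barcode, for 32285 genes. Reads were processed with Cell Ranger 6.1.2 against GRCm38/mm10, per the submitters' processing notes, while the matrix headers name an earlier Cell Ranger release. Seurat 4.0.2 and R 4.1.0 are also named in those notes. The series text says that ambient RNA was removed with SoupX and that the cells were integrated with Harmony. SoupX output need not be whole numbers and the deposited counts are, so the values used here were treated as uncorrected, and corrected values were not analysed here. The numbers of barcodes, 15663 and 17462, equal the numbers of cells that the series text gives after mapping. The gene annotation used by the authors is not given in the sources used here; of the 32285 identifiers, 32158 were found in GENCODE M21 (GRCm38), from which the coordinates were taken.

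Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. Doublets were scored with Scrublet through scanpy 1.11.5 within each library. Its automatic threshold marked 4 cells per library (0.0309% and 0.0269%), too few to have worked, and was replaced after the data had been seen by a maximum score of 0.2, which removed 483 and 408 cells (3.73% and 2.75%). Genes seen in at least 10 cells entered the choice of 2000 variable genes within the libraries. Counts per 10000 were log-transformed (log1p) and scaled, and 30 principal components were joined in a graph of 15 neighbours, keeping shared-neighbour (Jaccard) weights of at least 1/15. Leiden clusters were taken at resolution 1.0 with leidenalg 0.10.2. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3 were used.

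Clusters were named from markers fixed before the data were examined, with a rule set after they had been seen. A marker counted as enriched at a log2 ratio above 1 and a UMI in at least 10% of the cluster's cells (10 CPM added to each level). A cluster took the class with the highest mean marker enrichment among classes with at least 3 enriched markers. It stayed unnamed when none of its 10 leading genes was a marker of that class, or when another class had more markers there. It also stayed unnamed when at least 0.5 of the markers of an unrelated class were enriched, with a mean log2 enrichment above 0.5. Hepatocyte markers were exempt from this last check, so a cluster with hepatocyte transcripts could still be named for another class. Leading genes were ranked by fold, with 20 CPM added, among genes in at least 0.2 of the cluster's cells. T cell and NK cell or ILC1 markers were pooled for that comparison and compared as 1 lymphocyte class, a choice made after finer clustering and centring had left part of the Hep-ADKWT lymphocytes unnamed. Classes are called "-like" because they rest on markers. A named class may therefore differ from the study's own annotation, which was not used here.

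Cells are not replicates, and with 1 library per group no test was possible, so no p-value, standard error or number of changed genes is given. UMIs were summed over the cells of a class in each library and scaled to CPM of that class total. CPM carry exact 95% Poisson intervals, ratios exact conditional binomial intervals and shares exact (Clopper-Pearson) intervals. All of these cover counting error only, not variation between animals or preparations. Where 1 library held no UMI, the ratio was computed against a floor of 3 counts. Classes with at least 200 kept cells in each library were compared; those with at least 75 were added after the data had been seen and stand among the other observations.

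The 28 gene lists, the markers, the rule for named genes and the processing alternatives were fixed before the data were examined. A list entered with at least 5 genes of at least 50 UMIs in the class. Its median log2 ratio is given with an order-statistic interval over its genes, which are not independent, and with its percentile among 10000 random lists of the same size matched on mean expression, as a description of these libraries. The rule for named genes took those with at least 200 UMIs and a UMI in at least 5% of the cells of the class in either library, leaving out predicted genes, mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes, the hepatocyte list and markers of other classes. It named the 10 highest and 10 lowest ratios in Kupffer cell-like, LSEC-like and monocyte-like cells and the 5 highest and 5 lowest elsewhere. Any list member or marker could be named, first the 4 members of a list with the largest change, and Adk and the adenosine genes were named from 50 UMIs. After the data had been seen, a repeat of the rule left out genes with 20% or more of their UMIs estimated as hepatocyte-derived and named 10 genes at each end. Genes picked after their values were seen are described as such. The lists that lead the account of each class were picked after all medians had been seen: of 143 medians, 27 lay below and 50 above the central 95% of their random lists; with the hepatocyte profile subtracted, 21 and 25 of 109 did.

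The hepatocyte-derived fraction of a class was estimated as its share of UMIs in the hepatocyte list (29 genes) divided by that share in the hepatocyte-like cells of the same library. That fraction of the class total was spread over genes in the proportions of those hepatocyte-like cells and subtracted, with a minimum of 0.

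Alternatives for shares were a minimum of 1000 UMIs, at most 10% mitochondrial UMIs, doublets kept, resolutions 0.5 and 2.0, centring within libraries and immune cells as the denominator. Alternatives for ratios were edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors, a class total without hepatocyte, mitochondrial, ribosomal, haemoglobin and immunoglobulin genes, means over cells, each cell thinned to 1000 UMIs, doublets kept, at most 10% mitochondrial UMIs, cells strict for their own markers (at least 2, and fewer of every other class), and list minimums of 10 and 200 UMIs. Chosen after seeing the data were the doublet score, the pooled lymphocyte class, T and NK markers counted apart, clustering without 1437 hepatocyte-enriched (3-fold), haemoglobin, immunoglobulin and mitochondrial genes, a denominator without hepatocyte-like and erythroid-like cells, the hepatocyte subtraction, single hepatocyte-like clusters, and LSEC-like cells joined with vascular endothelial cell-like cells.

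The calculations were tested on simulated data drawn from the summed counts of 5 classes. Median recovered folds for 2-fold changes were 1.997 in lymphocyte-like (9015 genes), 1.99 in B cell-like (5620), 1.99 in LSEC-like (7553), 1.99 in hepatocyte-like (8104) and 1.95 in monocyte-like cells (4584); for 0.5-fold changes they were 0.506, 0.493, 0.495, 0.494 and 0.489. The 95% intervals held the true value for 94.9% to 95.6% of genes. Of 100 unchanged lists per class, 0 to 6 lay outside the central 95% of random lists, and 20 lists shifted by 0.5 log2 all lay at percentile 100. A mixed hepatocyte fraction of 15% was estimated as 14.9% to 15.1% in the 4 other classes. The receiving classes there held no list transcripts of their own, and the mixed profile was also the one used for the estimate. The list shift was added to the ratios directly. For the folds, intervals and unchanged lists, both libraries were drawn as independent Poisson counts from the Hep-ADKWT profile, with the set changes. Genes that vary together were not simulated. All of these checks therefore cover the arithmetic and not the assumptions.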

Results

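The libraries compare non-parenchymal cells from livers whose hepatocytes were engineered to overexpress adenosine kinase with cells from control livers. The library labelled Hep-ADKWT (WT) held 97135016 UMIs in 15663 barcodes, and the library labelled Hep-ADKTg (Tg) held 96481752 UMIs in 17462. After filtering, 12478 and 14445 cells remained, with medians of 4807 and 2783 UMIs and 1749 and 1175 genes per cell. Values are given throughout in the order WT, Tg, and values without a unit, list medians included, are log2 ratios of Tg over WT. Genotype, animal, cell preparation and library are the same division of the data, and no difference below has a replicate check.

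Adk (ENSMUSG00000039197, chromosome 14, 21052574–21448569, GRCm38) was not higher in the pooled hepatocyte-like cells of the library labelled Tg: its level was 708 (688–729) and 576 (568–583) CPM. In cluster 1, the hepatocyte-like cluster with many cells of both libraries (1279 and 1219), Adk stood at 993 (957–1030.3) and 1048 (1012–1084) CPM, a ratio of 1.05 (1.002–1.11). In cluster 10, which held the deepest hepatocyte-like cells (72 and 820), it stood at 453 (429–478) and 523 (514–532) CPM, a ratio of 1.15 (1.09–1.22). The direction of the pooled levels turned within both clusters, whose shares of the class differed between the libraries. Outside hepatocytes Adk stood at 21.3 and 70.3 CPM in lymphocyte-like, 25.9 and 89.0 CPM in B cell-like, 28.6 and 93.1 CPM in LSEC-like and 20.5 and 60.7 CPM in monocyte-like cells, and closer together at 114 and 117 CPM in pDC-like and 123 and 128 CPM in fibroblast or mesothelial cell-like cells. By estimate, 84.1% and 95.2% of these Adk UMIs were hepatocyte-derived in lymphocyte-like cells, 100% in B cell-like and LSEC-like cells of both libraries, 72.8% and 62.6% in monocyte-like, 11.5% and 34.5% in pDC-like and 16.1% and 39.2% in fibroblast or mesothelial cell-like cells. The values of 100% are the cap: there the estimate passed the counted Adk, so the subtraction can take away too much. The 3′ sequence of the transgene is not given in the sources used here, and a 3′ tag count may miss it. Adk thus checks neither label, and groups are named by the labels alone.

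**Figure D1:**
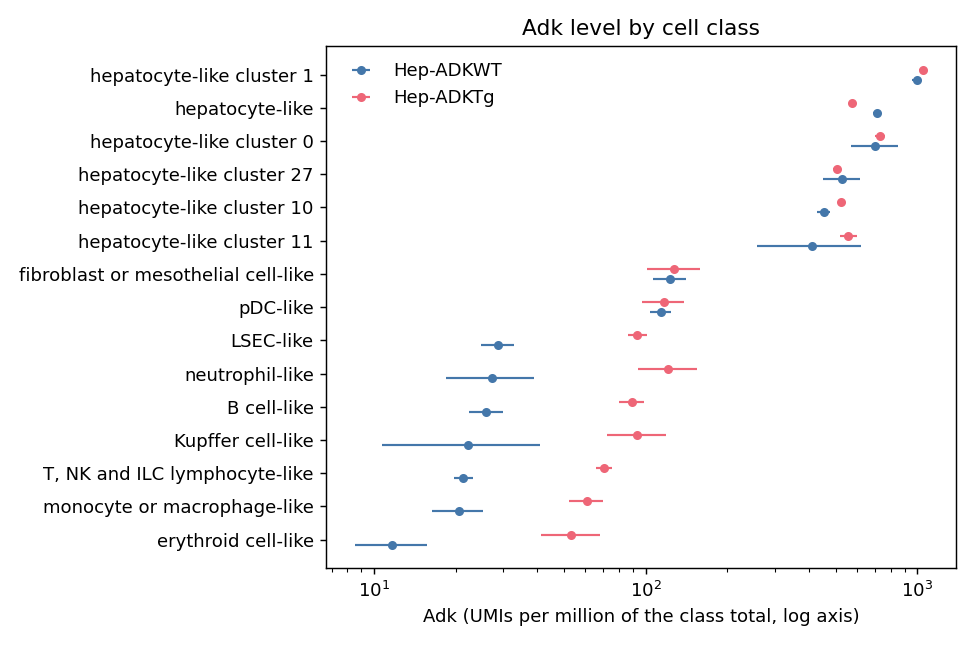
Adk in CPM of the class total (log axis) for each cell class and hepatocyte-like cluster in both libraries, with exact 95% Poisson intervals. Pooled hepatocyte-like cells stood at 708 CPM in the library labelled WT and 576 CPM in that labelled Tg, and LSEC-like cells at 28.6 and 93.1 CPM, of which 100% (the cap) was hepatocyte-derived by estimate.

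Hepatocyte-like cells made up 12.4% (11.8–12.96; 1544 cells) and 42.4% (41.6–43.2; 6121 cells) of the kept cells, a 3.42-fold higher share in the library labelled Tg. T, NK and ILC lymphocyte-like cells made up 36.7% (35.8–37.5; 4575 cells) and 17.3% (16.7–17.9; 2501 cells), and B cell-like cells 16.4% (15.8–17.1; 2046 cells) and 8.52% (8.07–8.99; 1231 cells). Liver sinusoidal endothelial cell (LSEC)-like cells, which line the sinusoids and clear macromolecules from blood, made up 13.3% (12.7–13.9; 1655 cells) and 16.4% (15.8–17.0; 2362 cells). Kupffer cell-like cells, a cluster named for the resident macrophages but not separated into macrophage types, made up 0.729% (0.588–0.895; 91 cells) and 1.43% (1.25–1.64; 207 cells), and monocyte or monocyte-derived macrophage-like cells 2.65% (2.38–2.95; 331 cells) and 2.24% (2.001–2.49; 323 cells). Plasma cell-like cells (2.49% (2.23–2.78; 311 cells) and 0.381% (0.287–0.495; 55 cells)) differed by a factor of 6.55, and plasmacytoid dendritic cell (pDC)-like cells made up 3.21% and 1.004%, neutrophil-like cells 2.58% and 1.36% and erythroid cell-like cells 3.75% and 1.68%. Vascular endothelial cell-like cells made up 0.561% and 2.03%, cholangiocyte-like cells 0.280% and 0.685%, fibroblast or mesothelial cell-like cells 1.09% and 0.609% and basophil or mast cell-like cells 0.497% and 0.104%. Clusters left unnamed held 3.45% and 3.91% of the cells. The minimum of 200 genes left out 1873 barcodes (12.0%) of the library labelled WT and 36 (0.206%) of that labelled Tg. Those of the library labelled WT had a median of 92.4% haemoglobin UMIs. Before filtering, 1717 and 230 barcodes held mostly haemoglobin UMIs, so the erythroid cell-like shares depend on that filter.

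The lymphoid shares depended on the denominator. Of immune cells alone (8139 and 4674), lymphocyte-like cells made up 56.2% and 53.5% and B cell-like cells 25.1% and 26.3%, while Kupffer cell-like cells made up 1.12% and 4.43%, monocyte-like cells 4.07% and 6.91%, neutrophil-like cells 3.96% and 4.21%, pDC-like cells 4.93% and 3.10% and plasma cell-like cells 3.82% and 1.18%. Without hepatocyte-like and erythroid-like cells, a denominator chosen after seeing the data, the LSEC-like share was 15.8% and 29.2%. Collagenase digestion can affect the yield of each type, which was not tested, and the hepatocyte-like cells had median depths of 1277 and 1130 UMIs. Clustered without hepatocyte-enriched and other free-RNA genes, hepatocyte-like cells made up 11.6% and 35.7% and unnamed clusters 5.83% and 12.3%. Clusters were named with all genes in that setting too, so it cannot tell whole hepatocytes from fragments or free RNA. Hepatocyte-like cells of the main setting had median mitochondrial shares of 0.385% and 1.56%. At resolution 0.5 the LSEC-like share ratio turned to a log2 of −0.18.

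**Figure D2:**
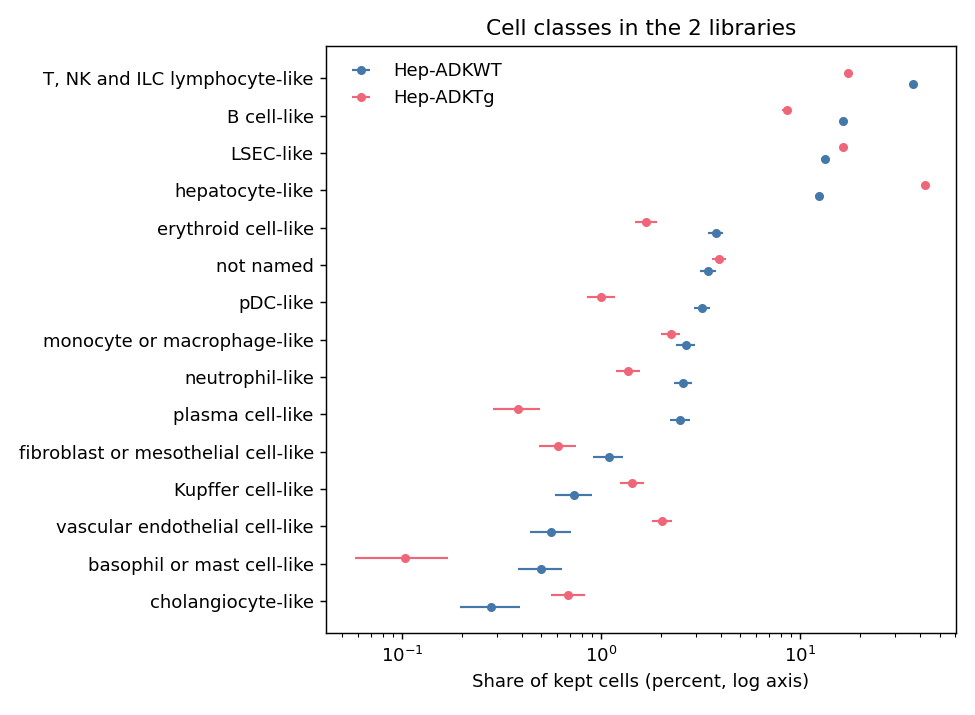
Share of kept cells in each class (percent, log axis) in both libraries, with exact 95% binomial intervals. Hepatocyte-like cells stood at 12.4% and 42.4%, lymphocyte-like cells at 36.7% and 17.3% and Kupffer cell-like cells at 0.729% and 1.43%.

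Several classes split into clusters by library. Cluster 3 held 92.7% and 0.731% and cluster 4 7.33% and 99.3% of the B cell-like cells. LSEC-like cells lay in clusters 8 (66.5% and 1.40%) and 19 (26.5% and 0.212%) in the library labelled WT and in clusters 6 (4.29% and 50.8%) and 7 (2.72% and 47.6%) in that labelled Tg. Lymphocyte-like cells lay mainly in clusters 5 (29.5% and 0.160%), 9 (24.8% and 0.0400%), 13 (15.1% and 0.240%) and 17 (11.4% and 0.600%) against 2 (5.03% and 72.1%) and 15 (1.29% and 23.4%). Hepatocyte-like cells lay in cluster 1 (82.8% and 19.9%) and cluster 0 (9.65% and 51.1%). The monocyte-like, Kupffer cell-like and erythroid cell-like classes were single clusters holding both libraries. With 1 library per group, a cluster mostly of 1 library may be that library and not a cell type.

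Hepatocyte transcripts were higher in the library labelled Tg in every other class compared. All 29 genes of the hepatocyte list, among them Alb, Apoa1 and Ttr, had higher CPM there, with list medians of 2.36 in B cell-like, 2.73 in LSEC-like, 2.58 in lymphocyte-like, 2.59 in erythroid cell-like and 2.24 in monocyte-like cells, all at percentile 100. The list took 1.80% and 12.7% of the UMIs of kept cells. By estimate, 4.18% and 16.6% of the UMIs of B cell-like cells, 4.72% and 17.8% of LSEC-like, 2.53% and 11.6% of lymphocyte-like, 2.28% and 10.1% of erythroid cell-like and 2.11% and 6.60% of monocyte-like cells were hepatocyte-derived. Some metabolic lists were read with and without that fraction. The antioxidant list had a median of 0.93 in B cell-like, 0.58 in T, NK and ILC lymphocyte-like and 0.28 in LSEC-like cells, and 0.072, −0.11 and −0.046 after the hepatocyte profile was subtracted. The nuclear oxidative phosphorylation list went from 0.25, 0.11 and 0.26 to 0.00024, −0.039 and 0.031, but in erythroid cell-like cells from 0.27 to −0.96. Erythroid cell-like cells carried lymphocyte transcripts in the library labelled WT, with 265 and 1 UMIs of Gzmb and a lymphocyte effector list median of −2.55 (10 of 10 lower).

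In monocyte or monocyte-derived macrophage-like cells, inflammatory genes were lower in the library labelled Tg. The class held both monocyte-like and dendritic cell-like cells, which parted only at resolution 2.0 (below), and its values pool both. The interferon-induced chemokines Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347–92328079) and Cxcl10, which recruit T cells, stood at 655 (631–680.1) versus 148 (135–162) CPM and 356 versus 97.51 CPM, 4.41-fold and 3.65-fold lower. Il1rn (ENSMUSG00000026981, chromosome 2, 24336853–24351494), the interleukin-1 receptor antagonist, stood at 54.7 (47.9–62.3) versus 9.12 (6.11–13.1) CPM, a log2 ratio of −2.59 (−3.20 to −2.02). It opposes interleukin-1 and belongs to the alternative activation and resolution list, not to the inflammatory list. Il12b (−2.50), Ccl4 (−1.44), Cxcl2 (−0.995), Tnf (−0.91), Ccl5 (−0.84) and Il1b (−0.76) were lower too, while Il18 stood at 0.077. In the inflammatory cytokine list 14 of 15 genes were lower, with a median of −0.84 (−1.44 to −0.36; percentile 0). In the NF-kB feedback and target list 19 of 20 were lower, with a median of −0.56 (−0.65 to −0.30; percentile 0): Tnip1 stood at 55.0 versus 24.2 CPM, Sod2 at 186 versus 85.9 CPM, Tnfaip3 (A20) at 42.7 versus 20.1 CPM, Tnfaip2 at 199.6 versus 117 CPM and Nfkbia at 266 versus 219 CPM, and Ier3 was the exception (0.16).

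Antigen presentation by MHC class II went the other way. H2-Ab1 stood at 2721 versus 4317 CPM, H2-Aa at 2900.2 versus 3939 CPM, H2-Eb1 at 2312 versus 3161 CPM and the invariant chain Cd74 at 6827 versus 8927 CPM, and 8 of 9 genes were higher (median 0.39 (0.29 to 0.45; percentile 100)). The interferon response list was mixed (15 of 23 higher, median 0.10 (−0.23 to 0.33; percentile 99.3)), with Ifi47 at −1.07, Ifi203 at −0.48, Zbp1 at −0.44 and Ifi27l2a at 0.45. At resolution 2.0 its median was 0.31 (−0.036 to 0.72) in finer cluster 23 and −0.25 (−0.45 to 0.12) in finer cluster 30, the parts into which the class fell. MHC class I genes were lower (10 of 12, median −0.29 (−0.41 to −0.0024; percentile 0.0600)). Of the alternative activation list, Arg1 stood at 20.5 versus 86.8 CPM and Retnla at 0 and 65 UMIs, at least 28.9-fold higher, while Il1rn (given above), Msr1 (−0.67) and Axl (−0.60) were lower (median −0.33 (−0.60 to 0.9997; percentile 0.650)). In the fatty acid and sterol synthesis list 13 of 18 genes were lower, with Sqle at −0.91, the fatty acid desaturase gene Scd2 at −0.79, Hmgcs1 at −0.70 and Idi1 at −0.56 (median −0.31 (−0.56 to 0.11; percentile 0.530)). Of the adenosine genes, the receptor Adora2a stood at 23.4 versus 8.81 CPM, Pnp at 255 versus 201 CPM, Dpp4 at 44.8 versus 69.5 CPM and Entpd1 (CD39) at 0.33.

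The 10 lowest monocyte-like genes under the fixed rule were Il1rn, Cxcl9, Gbp5 (−1.95), Cxcl10, Gbp2 (−1.69), Cxcr6 (−1.64), Bcl11b (−1.58), Lck (−1.51), Cd2 (−1.48) and Hivep3 (−1.47), of which Cxcr6, Bcl11b, Lck and Cd2 are lymphocyte transcripts; the lymphocyte effector list had a median of −0.76 (−1.64 to −0.29; percentile 0). The 10 highest were Hspa1a (6.84 versus 62.3 CPM), encoding a heat shock protein, Lcn2 (11.6 versus 90.9 CPM) and hepatocyte-derived transcripts: Mup17, Mup11, Wfdc21, Pzp, Mup16, Saa2, Mup1 and Saa1 (3.78 to 2.88). Lcn2 stood at 251 and 517 CPM in hepatocyte-like cells but at 2233 and 2836 CPM in neutrophil-like cells. Its source in monocyte-like cells was not tested. Without the genes left out for their estimated hepatocyte-derived UMIs, P2ry14 (18.4 versus 55.0 CPM), Rab7b (45.1 versus 111 CPM), Cd36 (23.1 versus 54.4 CPM), a fatty acid translocase, and Ppt1 (204 versus 475 CPM), a lysosomal thioesterase, were among the highest. At resolution 2.0 the class parted into finer cluster 23 (185 and 202 cells), led by Cst3, Plbd1, MHC class II genes, Naaa and Cd209a, and finer cluster 30 (146 and 120), which was monocyte-like. The naming rule called finer cluster 23 cDC1-like, a dendritic cell type, although Cd209a is a fixed marker of another dendritic cell type. The NF-kB list median was −0.40 in cluster 23 and −0.73 in cluster 30. The MHC class II median was 0.29 (0.17 to 0.34; 9 of 9 higher) and 0.19 (−0.85 to 0.40; 6 of 9 higher). Without cells holding a UMI of a T or NK cell marker (54.7% and 40.9% left out), the NF-kB median was −0.58 and the inflammatory median −0.43 (−1.77 to 0.0052). In marker-strict cells, of which the library labelled Tg kept 47, the MHC class II median turned to −1.45, H2-Ab1 to −1.61 and Cxcl2 to 0.29, and H2-Aa, H2-Eb1 and Cd74 turned too. Thinned to 1000 UMIs, Il1b turned to 0.33 and Nfkbia to 0.13.

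In LSEC-like cells, 10 of 15 genes of the angiocrine and Notch list and 14 of 15 of the adhesion and capillarisation list were lower in the library labelled Tg. Thbd (ENSMUSG00000074743, chromosome 2, 148404466–148408188), the anticoagulant thrombomodulin, stood at 375 (361–389.6) versus 187 (176–198) CPM. The Wnt pathway ligands Wnt2 (ENSMUSG00000010797, chromosome 6, 17988940–18030585) and Wnt9b and the Wnt enhancer Rspo3, which maintain pericentral hepatocyte zonation, stood at 543 (526–561) versus 346 (332–360.4) CPM, 27.9 versus 15.8 CPM and 98.6 versus 57.4 CPM. The Notch ligand Dll1 (−0.82) and the receptor Kit (829 versus 553 CPM) were lower as well, whereas Bmp2 (0.022) and Hgf (74.3 versus 90.3 CPM) were not. The angiocrine and Notch list had a median of −0.46 (−0.82 to 0.17; percentile 0). The median was −0.25 after hepatocyte subtraction, −0.31 with doublets kept, −0.20 at most 10% mitochondrial UMIs and −0.23 in marker-strict cells. At most 10% mitochondrial UMIs, Rspo3 turned to 0.13. Rspo3 and Wnt9b led cluster 23 of resolution 1.0, which was named vascular endothelial cell-like and held 51 and 257 cells. With vascular endothelial cell-like cells joined to the class, a choice made after seeing the data, Rspo3 turned to 1.37 and Wnt9b to 0.53, while Thbd stood at −0.72 and Wnt2 at −0.54. Of the list, 9 of 15 genes were then lower (median −0.21).

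The endothelial adhesion and capillarisation list had a median of −0.34 (−0.58 to −0.18; percentile 0.0600), with Plvap, the diaphragm protein of capillary endothelium, at 229.6 versus 126 CPM, Cd9 at 246 versus 146 CPM, the endothelial nitric oxide synthase Nos3 at 127 versus 84.9 CPM and Icam2 at −0.57. That median was −0.16 after subtraction, −0.22 with DESeq2 factors, −0.20 in marker-strict cells and −0.18 with vascular endothelial cell-like cells joined, where 9 of 15 genes were lower and Plvap stood at −0.083. Scavenging genes were mixed, with Stab1 at 1502 versus 1177 CPM, Stab2 at 1418 versus 1128 CPM, Scarb1 at −0.62 and Lyve1 at 239 versus 315 CPM (7 of 11 lower, median −0.22 (−0.35 to 0.29; percentile 4.35)). Interferon response genes were higher in 18 of 24 cases (median 0.25 (0.0053 to 0.50; percentile 100)): Ifit1 stood at 15.6 versus 30.6 CPM, Ifi44 at 37.2 versus 68.8 CPM, Isg15 at 20.9 versus 38.3 CPM and Rsad2 at 96.9 versus 142 CPM, and the median was 0.42 after subtraction and 0.16 as a mean over cells. Of the adenosine genes, the receptor Adora2a stood at 13.3 versus 25.5 CPM (0.94 (0.56 to 1.32)), Ada at 92.7 versus 56.8 CPM, Pnp2 at −0.53, the transporter Slc29a1 at 706 versus 563 CPM and Dpp4 at 679 versus 533 CPM; 7 of 9 were lower (median −0.33 (−0.71 to 0.94; percentile 2.26); −0.15 after subtraction, −0.21 with TMM factors, −0.20 with DESeq2 factors and −0.18 in marker-strict cells).

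The 10 lowest LSEC-like genes were Ccl5 (114 versus 43.6 CPM), Zbtb16 (−1.34), Rac2 (−1.32), Ltc4s (116 versus 46.9 CPM), Bcam (58.6 versus 23.9 CPM), S100a6 (−1.28), Dbp (201 versus 83.2 CPM), Cdc42ep3 (−1.27), Syt7 (−1.26) and Cd52 (−1.26). Ccl5, Rac2 and Cd52 are leukocyte transcripts, and the lymphocyte effector list stood at −1.43 in these cells (8 of 8 lower). With vascular endothelial cell-like cells joined Bcam stood at −0.62 and Cdc42ep3 at −0.59. As a mean over cells Rac2 turned to 0.088 and Ccl5 stood at −0.48. The 10 highest, Mup18, Hamp, Mup17, Mup9, Lcn2, Saa1, Mup11, Saa4, Saa2 and Mup16 (4.45 to 3.45), were hepatocyte-derived by estimate. Without such genes, AY036118 (154 versus 551 CPM), the immediate early gene Egr1 (13.7 versus 41.4 CPM), Wdfy1 (17.0 versus 41.0 CPM) and Adamts1 (96.5 versus 169.8 CPM) were among the highest. LSEC-like cells had median depths of 4509 and 2265.5 UMIs, and the median over all 10710 genes was −0.14, against −0.022 with TMM factors.

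In T, NK and ILC lymphocyte-like cells, cytotoxic effector genes were lower in the library labelled Tg. The granzymes Gzmb (ENSMUSG00000015437, chromosome 14, 56258838–56262260) and Gzma stood at 434 (427–442) versus 275 (266–285) CPM and 607 versus 412 CPM, perforin (Prf1) at 88.7 versus 64.9 CPM and Tnfrsf9 (4-1BB) at −0.49. Cxcr6 (575 versus 439 CPM) and Id2 (1447 versus 1124 CPM) were lower, while Ifng (65.3 versus 75.2 CPM), Fasl (0.21) and Ccl4 (85.3 versus 110.4 CPM) were higher. In the effector list 15 of 18 genes were lower, with a median of −0.36 (−0.44 to −0.20; percentile 0), or −0.23 after subtraction. NK cell or ILC1-like clusters held 694 of 4575 cells in the library labelled WT and 104 of 2501 in that labelled Tg, but at resolution 2.0 a further cluster of 86 and 449 cells took that name, so the make-up of the class depended on the clustering.

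Immediate early and dissociation genes were higher in 12 of 19 cases (median 0.18 (−0.15 to 0.70; percentile 99.99)), among them the heat shock genes Hspa1a (6 and 167 UMIs, 67.1-fold) and Hspa1b (1.10 versus 37.2 CPM, 33.9-fold), Jun (0.79), Fos (0.70) and Dusp1 (0.61). Interferon response genes were higher in 19 of 23 cases (median 0.18 (0.031 to 0.34; percentile 100)), with Ifi27l2a at 260.1 versus 486 CPM, Rtp4 at 0.38, Bst2 at 0.36 and Irf9 at 0.34. Thinned to 1000 UMIs the median was 0.11, and with doublets kept 0.36. MHC class I genes were lower in 12 of 12 cases, with a median of −0.22 (−0.27 to −0.17) at percentile 0.180. The median over all 11488 genes of the class was itself −0.099, against −0.037 with TMM factors. Of the cell cycle list 10 of 11 were lower, with Mki67 at −0.41 and a median of −0.37 (−0.66 to −0.0033) at percentile 0.160. Of the adenosine genes, Adora2a stood at 43.9 versus 29.8 CPM, Ada at −0.30 and Slc29a1 at 0.31 (list median 0.020 (−0.30 to 0.31; percentile 91.9)). The 5 lowest genes were Lgals3 (54.6 versus 16.8 CPM), which encodes galectin-3, Styk1 (19.7 versus 6.65 CPM), Napsa (−1.12), the NK receptor gene Klra7 (47.9 versus 22.9 CPM) and Lrrc61 (−1.04), and the 5 highest were Hspa1b and the hepatocyte-derived Hamp, Mup18, Mup17 and Mup9. In marker-strict cells, of which the library labelled Tg kept 52, the effector median was −0.85, Klra7 turned to 0.038 and Prf1 to 0.15. Ifng (−1.05), Fasl (−0.84), Dusp1 (−0.21) and Irf9 (−0.24) turned there as well, and Ifng also when thinned (−0.11). After subtraction Slc29a1 turned to −0.15.

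In B cell-like cells, the stress genes Hspa1b (0.894 versus 59.7 CPM, 66.7-fold), Jun (95.2 versus 195 CPM) and Dusp1 (0.52) were higher in the library labelled Tg, and 12 of 18 immediate early and dissociation genes were higher (median 0.21 (−0.24 to 0.41; percentile 99.97)); after hepatocyte subtraction Dusp1 turned to −0.20. Pde3b, a cyclic nucleotide phosphodiesterase, stood at 20.2 versus 55.3 CPM. The interferon genes Bst2 (54.9 versus 94.9 CPM), Irf7 (0.49), Ifi27l2a (411 versus 524 CPM) and Zbp1 (0.33) were higher, and 11 of 18 list members were higher (median 0.13 (−0.099 to 0.33; percentile 99.5); 0.057 as a mean over cells, 0.071 with genes from 10 UMIs, 0.23 with TMM factors and 0.38 in marker-strict cells). NF-kB genes were lower in 14 of 18 cases, with Icam1 at −0.71, Cflar at −0.61 and Nfkb1 at −0.48 (median −0.29 (−0.48 to −0.091; percentile 1.31)), but the median was −0.095 after subtraction. The interferon-inducible Ifi208 (ENSMUSG00000066677, chromosome 1, 173673675–173698395) was lowest at 32.2 (28.3–36.4) versus 5.34 (3.34–8.08) CPM, followed by Mir142hg (51.1 versus 20.9 CPM), Zfp865 (−1.26), Ccl5 (−1.20) and Arid3a (21.3 versus 9.70 CPM). Ccl5 turned to 1.35 with doublets kept and 0.78 in marker-strict cells. Beside Hspa1b the highest genes were Mup18, Hamp, Ang and Mup17, hepatocyte-derived by estimate, and the median over all 9392 genes was −0.15, against −0.043 with TMM factors.

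In hepatocyte-like cells, chaperones of the endoplasmic reticulum were higher in the library labelled Tg. Hspa5 (BiP; ENSMUSG00000026864, chromosome 2, 34771970–34777547) stood at 326 (312–340.5) versus 567 (559.6–574) CPM, Herpud1 (ENSMUSG00000031770, chromosome 8, 94386438–94395377) at 228 (217–240.3) versus 403 (397–409) CPM, Pdia4 at 83.5 versus 142 CPM and Calr at 572 versus 882 CPM, whereas Atf4 (−0.54) and Trib3 (−0.61) were lower. In cluster 1 alone Hspa5 stood at 1.31, Herpud1 at 0.84, Pdia4 at 1.10 and Calr at 1.01, and Atf4 turned to 0.24. In the unfolded protein response list 12 of 15 genes were higher (median 0.47 (0.15 to 0.63; percentile 100); 0.82 as a mean over cells, 1.09 thinned, 1.22 at most 10% mitochondrial UMIs, 0.81 with TMM factors and 0.79 with DESeq2 factors). The fibrinogen genes Fgb (2146 versus 4155 CPM), Fga (0.89) and Fgg (0.84), acute phase products, led the hepatocyte list, of which 22 of 29 were higher, while Gnmt, which consumes S-adenosylmethionine, was lower (−0.90). In the transmethylation list, which holds the pathway that yields adenosine, 11 of 13 genes were lower, with Ahcy, the enzyme that splits S-adenosylhomocysteine into adenosine and homocysteine, at 197 versus 127 CPM, Dnmt1 at −0.63, Prmt1 at −0.60, Tet3 at −0.42 and Mat2a at 0.17; its median (−0.37 (−0.63 to −0.071; percentile 22.1)) lay inside the range of random lists.

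Glycolysis and hypoxia genes were lower in 12 of 14 cases, with Eno1 at −0.93, Bnip3 at −0.78, Pgk1 at −0.55 and Gpi1 at −0.53 (median −0.50 (−0.78 to −0.017; percentile 1.92)). Interferon genes were higher in 14 of 18 cases (median 0.44 (0.12 to 1.501; percentile 100); 0.83 in cluster 1 alone, 0.77 with TMM factors and 0.26 with genes from 200 UMIs), with Ifit1 at 10 and 340 UMIs and Usp18 at 1.501, but Ifi203 at −2.44 and Ifi27l2a at −1.77. Among the adenosine genes Pnp stood at 99.5 versus 63.8 CPM, Dpp4 at 27.4 versus 41.6 CPM and Adora1 at 0.19 (list median 0.050 (−0.64 to 0.60; percentile 93.8)). The 5 highest genes were Ctrb1, Mup18 (32.3 versus 198 CPM), Slc8a1 (8.23 versus 41.9 CPM), Noct (20.7 versus 94.3 CPM) and Wdfy1 (5.06 versus 21.7 CPM). The pancreatic protease gene Ctrb1 stood at 0 and 424 UMIs, 22.5-fold higher against the floor of 3 counts. In the library labelled Tg, Ctrb1 stood at 10.7 CPM in hepatocyte-like cells and higher, at 22.5, 18.9 and 15.3 CPM, in LSEC-like, B cell-like and lymphocyte-like cells. The lowest was Socs2, an inhibitor of growth hormone signalling (22.5 (18.9–26.5) versus 1.99 (1.58–2.48) CPM), followed by the leukocyte transcripts Rac2 (−3.13), Crip1 (−3.12), Ptpn18 (−3.03) and Cd52 (−2.92), beside lymphocyte effector and MHC class II medians of −2.74 and −2.32. The median over all 10715 genes was −0.24, against 0.088 with TMM factors, and different clusters held most hepatocyte-like cells in the libraries.

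In erythroid cell-like cells, the lowest genes in the library labelled Tg were the lymphocyte transcripts Gzmb (−6.37 (−11.68 to −3.88)), Cd7 (333 and 2 UMIs), Fyb (−3.68), Cxcr6 (−3.19) and Il2rb (−3.14), and the highest the hepatocyte-derived Mup17, Mup11, Mup16, Saa1 and Saa2 (4.31 to 3.10). Isg15, an interferon-induced gene, stood at 115 versus 197 CPM, but its log2 ratio turned from 0.78 to −0.19 as a mean over cells. The median over all 2575 genes was −0.93, against −0.36 with TMM factors and −0.29 with DESeq2 factors.

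**Figure D3:**
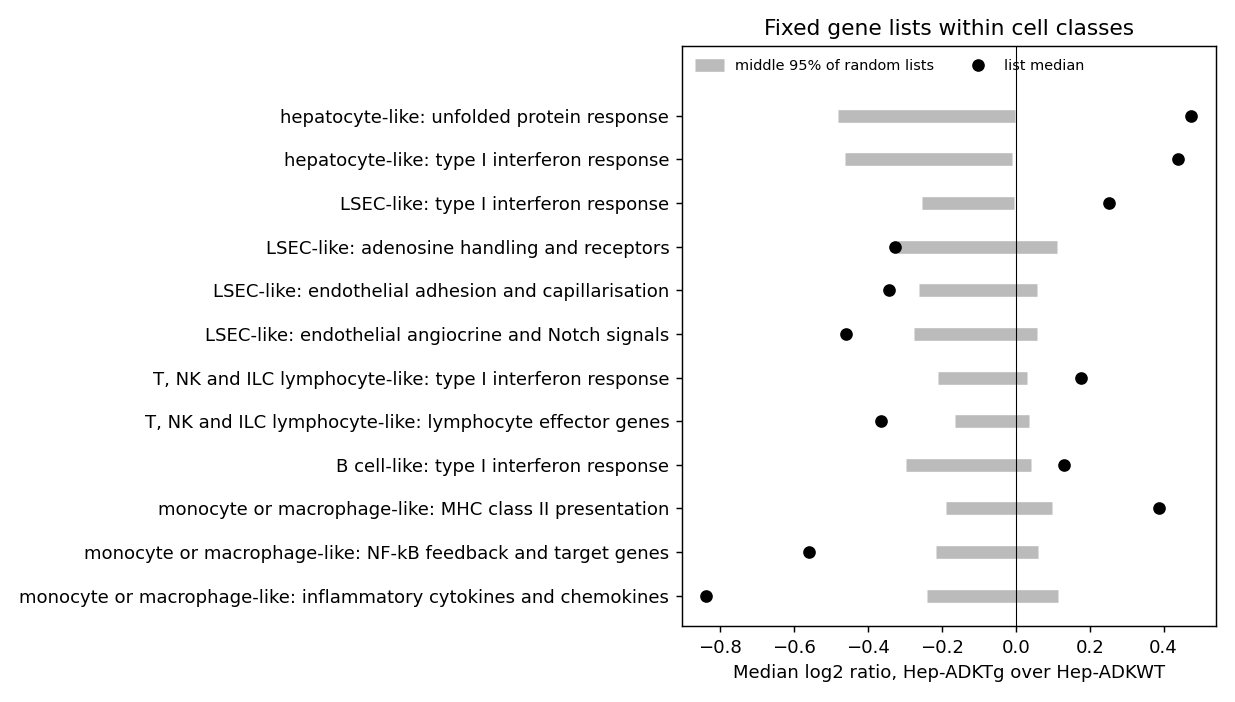
Median log2 ratio (Tg over WT) of 12 gene lists, picked after all medians had been seen, in the class named beside each. Bars show the central range of random lists matched on size and mean expression, not an interval of the median. The monocyte-like inflammatory list stood at −0.84 as counted and the LSEC-like angiocrine list at −0.46. After subtraction of the hepatocyte profile, which is not drawn, they stood at −0.77 and −0.25.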

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

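No test bears on either of these results, and none was chosen for them after they were seen. In the library labelled Tg, 14.9% of barcodes (2604) had over 20% mitochondrial UMIs and were left out of every comparison, against 9.05% (1418) in the library labelled WT; they stand out as a signal in cells that no comparison used. A cluster led by the pancreatic acinar transcripts Ctrb1, Prss2, Try5, Pnlip and Cpa1 held 18 cells of the library labelled Tg and 0 of 12478 kept cells of that labelled WT, which allows a share of up to 0.0240% (3 counts of that total); it was unnamed and entered no comparison.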

How the results depend on the processing

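No cause of a shift between settings was tested, and the settings named as added were chosen after seeing the data. No paired analysis was possible because each group has 1 library, numbered 1 in its own group, and no result comes from a test. Of the alternative values for the 10 shares, 51 stayed within the counting interval, 31 moved beyond it and 5 reversed. A change of sign counts as a reversal where the interval of the value as reported excludes 0; other sign changes stand with the values that stayed or moved. For the leading list medians these numbers were 123, 12 and 1, and for the other list medians 1275, 123 and 12. For genes they were 1674, 632 and 33, leaving out Adk in hepatocyte-like cells. These genes were taken by the rule for named genes, by its repeat or for the text, and not all of them are printed. Marker-strict cells were not used for erythroid cell-like cells, of which 1 remained in the library labelled Tg. In that library 59 B cell-like, 52 lymphocyte-like, 47 monocyte-like and 886 LSEC-like cells remained. Hepatocyte transcripts can lower these numbers, because a cell with as many hepatocyte markers as own markers was left out.

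Shares are given as log2 Tg over WT. Lymphocyte-like cells (−1.08) stood at −0.77 from 1000 UMIs, −0.91 at most 10% mitochondrial UMIs, −0.94 with doublets kept, −0.98 at resolution 2.0, −0.95 with centring, −0.071 of immune cells, −0.50 without hepatocyte-like and erythroid-like cells (added), and −0.57 at resolution 2.0 and −0.54 with centring when T and NK markers were counted apart (added). B cell-like cells (−0.94) stood at −0.66 from 1000 UMIs, −0.83 at most 10% mitochondrial UMIs, −0.81 with centring, 0.067 of immune cells, a reversal, and −0.36 without hepatocyte-like and erythroid-like cells. LSEC-like cells (0.30) stood at 0.48 from 1000 UMIs, −0.18 at resolution 0.5, a reversal, 0.19 at resolution 2.0 and 0.89 without those 2 classes. Hepatocyte-like cells (1.78) stood at 1.94 from 1000 UMIs, 1.59 and 2.45 at resolutions 0.5 and 2.0, 1.53 with centring and 1.62 when clustered without free-RNA genes (added). Monocyte-like cells (−0.25) stood at −0.49 at resolution 2.0 and reversed to 0.76 of immune cells and 0.34 without hepatocyte-like and erythroid-like cells. Of immune cells, and without those 2 classes, Kupffer cell-like cells (0.97) stood at 1.99 and 1.56, neutrophil-like cells (−0.92) at 0.091, a reversal, and −0.34, pDC-like cells (−1.68) at −0.67 and −1.09, and plasma cell-like cells (−2.71) at −1.70 and −2.13; from 1000 UMIs neutrophil-like cells stood at −0.64 and pDC-like cells at −1.39. The denominators move shares by construction; for the others the cause was not tested.

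With the hepatocyte profile subtracted (added), the B cell-like medians reversed for MHC class II (−0.15 to 0.039), fatty acid and sterol synthesis (0.31 to −0.23) and fatty acid oxidation and PPAR target genes (0.55 to −0.027), and the oxidative phosphorylation median reversed in lymphocyte-like (0.11 to −0.039) and erythroid cell-like cells (0.27 to −0.96); the LSEC-like adhesion median went from −0.34 to −0.16 and the monocyte-like MHC class II median from 0.39 to 0.45. In marker-strict cells the medians reversed for lymphocyte-like MHC class II (−0.54 to 2.32) and oxidative phosphorylation (−0.11) and for monocyte-like MHC class II (−1.45) and cell cycle (0.19 to −0.63), and moved for B cell-like interferon (0.13 to 0.38), lymphocyte-like effector (−0.36 to −0.85) and monocyte-like NF-kB genes (−0.56 to −0.83). With doublets kept the lymphocyte-like MHC class II median reversed to 0.086 and the interferon median went from 0.18 to 0.36. The hepatocyte-like oxidative phosphorylation median (−0.31) reversed to 0.0042 in cluster 1 alone (added), 0.026 with TMM and 0.014 with DESeq2 factors. The unfolded protein response median there (0.47) stood at 0.82 as a mean over cells, 1.09 thinned, 1.22 at most 10% mitochondrial UMIs, 0.70 in cluster 1, 0.81 with TMM and 0.79 with DESeq2 factors. Beyond the subtraction and the fewer cells, the cause was not tested.

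Among genes, Ccl5 in B cell-like cells (−1.20) reversed to 1.35 with doublets kept and 0.78 in marker-strict cells, Rac2 in LSEC-like cells (−1.32) to 0.088 as a mean over cells, and Klra7 in lymphocyte-like cells (−1.06) to 0.038 in marker-strict cells. Marker-strict cells also reversed Dusp1 (0.61 to −0.21), Fasl (0.21 to −0.84), Ifng (0.20 to −1.05), Irf9 (0.34 to −0.24) and Prf1 (−0.45 to 0.15) in lymphocyte-like cells and Cd74 (0.39 to −1.45), H2-Aa (0.44 to −1.93), H2-Ab1 (0.67 to −1.61), H2-Eb1 (0.45 to −2.54) and Cxcl2 (−0.995 to 0.29) in monocyte-like cells. Thinning reversed lymphocyte-like Ifng (−0.11), monocyte-like Il1b (−0.76 to 0.33) and Nfkbia (−0.29 to 0.13) and LSEC-like Arntl (0.48 to −0.022). Subtraction reversed B cell-like Dusp1 (0.52 to −0.20) and lymphocyte-like Slc29a1 (0.31 to −0.15). In hepatocyte-like cells Atf4 (−0.54) reversed to 0.24 in cluster 1, and mt-Nd3 (−0.30) to 0.41 as a mean over cells, 0.62 thinned, 1.46 at most 10% mitochondrial UMIs, 0.027 with TMM and 0.014 with DESeq2 factors. At most 10% mitochondrial UMIs reversed LSEC-like Rspo3 to 0.13. With vascular endothelial cell-like cells joined (added), Rspo3 (−0.78) and Wnt9b (−0.82) in LSEC-like cells turned to 1.37 and 0.53, through the cells added. In erythroid cell-like cells, as a mean over cells and thinned, Atpif1 (0.43) reversed to −0.31 and −0.025, and Isg15 (0.78) to −0.19 and −0.17. Adk in hepatocyte-like cells (−0.30) stood at −0.18 with the reduced class total, −0.35 as a mean over cells, −0.36 thinned and −0.47 at most 10% mitochondrial UMIs, and reversed to 0.033 with TMM and 0.021 with DESeq2 factors; within single clusters (added) it was 0.059 in cluster 0, 0.077 in cluster 1, 0.21 in cluster 10, 0.44 in cluster 11 and −0.062 in cluster 27. The cause was not tested. Thinning to 1000 UMIs left out 38.5% and 44.2% of hepatocyte-like, 18.7% and 27.2% of LSEC-like cells, and 25.3% and 31.9% of Kupffer cell-like cells, so depth limits these classes.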

Other observations

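The classes here were added after the data were seen, and the tests of fragments, 3′ ends, swapped labels, doublets, the mix of monocytes and dendritic cells and the dissociation response were chosen only after the result was seen. Kupffer cell-like cells (91 and 207) had higher cell cycle and lower MHC class II genes in the library labelled Tg. They were 1 cluster led by the C1q genes, Aif1, Csf1r, Cx3cr1 and Fcgr4, and macrophage types within it were not separated. Cells strict for Kupffer cell markers numbered 30 and 6, and a different mix of macrophage types between the libraries was not tested. Cd5l, a scavenger receptor family protein of Kupffer cells, stood at 114 (84.6–149) versus 584 (529.8–643) CPM, Clec4f at 82.5 (58.1–114) versus 314 (275–358) CPM, Vsig4 at 91.4 versus 192 CPM and the proliferation marker Mki67 at 26.7 versus 278 CPM. In these cells 12 of 12 cell cycle genes were higher (median 1.31 (0.61 to 2.78; percentile 100)) and so were 11 of 15 complement and scavenging genes (median 1.07 (−0.11 to 1.93; percentile 100)), whereas C1qa stood at 3863 versus 3555 CPM. Adgre1 (386 versus 243 CPM) and the monocyte markers Cx3cr1 (1016 versus 448 CPM), Ccr2 (515 versus 225 CPM) and Lyz2 (5495 versus 2311 CPM) were lower. H2-Ab1 stood at 8198 versus 3986 CPM, Cd74 at 19536 versus 10383 CPM and Cd207 (langerin) at 606 versus 234 CPM, and 8 of 8 MHC class II genes were lower (median −0.92 (−1.32 to −0.32; percentile 0)). Of the inflammatory genes, Ccl4 (165 versus 611 CPM), Cxcl2 (24.5 versus 166 CPM) and Il1b (225 versus 495 CPM) were higher and Ccl5 (1215 versus 228 CPM) lower. Dissociation genes picked after their values were seen were higher too: Fos (221 versus 515 CPM), Hspa1a (1 and 65 UMIs) and Hspa1b (0 and 74 UMIs). Egr1 stood at 0.43 (−0.10 to 0.98). Estimated hepatocyte-derived shares of UMIs were 11.1% and 21.6%; with that profile subtracted the complement median was 1.16 and the MHC class II median −0.74.

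The interferon response list was also higher in pDC-like cells (16 of 18; median 0.57 (0.16 to 1.12; percentile 100)), with Isg15 at 40.4 versus 92.4 CPM and Ifi44 at 0.85, and in neutrophil-like cells (11 of 14; median 0.36 (−0.55 to 0.64; percentile 99.97)), with Ifi27l2a at 0.77 and Oasl2 at 0.64. It stood at 0.038 (−0.19 to 0.30; percentile 58.9) in Kupffer cell-like and −1.04 (−2.73 to 0.78; percentile 28.5) in erythroid cell-like cells. In pDC-like cells Ccl4 stood at 40.4 versus 282 CPM. Fibroblast or mesothelial cell-like cells (136 and 88) had higher immediate early and dissociation genes in the library labelled Tg in 19 of 20 cases (median 2.39 (0.75 to 2.95; percentile 100)), with Egr1 at 44.9 versus 755 CPM and Fos at 52.5 versus 796 CPM, and the B cell chemokine Cxcl13 stood at 434 versus 3146 CPM. Their NF-kB list was higher in 11 of 12 cases (median 0.75 (0.24 to 1.42; percentile 100)), as were 4 of 6 inflammatory genes (median 1.94 (−0.22 to 5.68; percentile 100)). The inflammatory list of Kupffer cell-like cells had 5 of 8 higher (median 0.76 (−2.41 to 2.76; percentile 99.8)). Of 86 list medians in the added classes, 14 lay below and 29 above the central 95% of their random lists; with the hepatocyte profile subtracted, 10 and 15 of 80 did.

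The following genes were picked after their values were seen. Ide (ENSMUSG00000056999, chromosome 19, 37268743–37337852), the insulin-degrading enzyme, was lower in the library labelled Tg in lymphocyte-like (76.3 versus 37.1 CPM), LSEC-like (98.6 versus 47.6 CPM) and hepatocyte-like cells (145 versus 64.8 CPM). Its interval held 0 in B cell-like (−0.31 (−0.65 to 0.026)) and fibroblast or mesothelial cell-like cells (−0.45 (−0.98 to 0.050)). The mitochondrial transcript mt-Nd3 was lower at −1.11 in lymphocyte-like, −1.004 in B cell-like, −0.74 in LSEC-like and −0.30 in hepatocyte-like cells, where it turned to 0.62 when thinned and under other settings, while Wdfy1 was higher at 1.01, 0.76, 1.27 and 2.10. Ifi208 stood at 190 versus 3 UMIs in LSEC-like and −0.80 in lymphocyte-like cells. The predicted gene Gm17167 (ENSMUSG00000091542, chromosome 4, 42206998–42235313) stood at 1826 versus 0 UMIs in LSEC-like cells, 555-fold lower against the floor of 3 counts. The clock output gene Dbp stood at −1.27 in LSEC-like, −0.88 in hepatocyte-like and −1.28 in fibroblast or mesothelial cell-like cells but 0.32 in lymphocyte-like cells, with Nr1d1 at −0.71, Per3 at −0.98 and Arntl at 0.48 in LSEC-like cells, where thinning turned Arntl to −0.022. Arntl stood at −0.47 (−1.16 to 0.29) in hepatocyte-like and −0.40 in lymphocyte-like cells. Collection times are not given in the sources used here. In hepatocyte-like cells the acute phase genes Saa1 (3554 versus 7368 CPM), Lcn2 (251 versus 517 CPM) and Hamp (347 versus 659 CPM) and the stress cytokine gene Gdf15 (10.1 versus 32.2 CPM) were higher. Their log2 ratios were 1.05, 1.04, 0.92 and 1.67, against 0.25, 0.39, 1.30 and 2.77 in cluster 1 alone.

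Adk in hepatocyte-like cells stood close to its level in the library labelled WT, although the labels give overexpression in those cells. Cell fragments or free RNA hiding a difference of 1.5-fold or more are argued against by cluster 10, where cells with median depths of 43188 and 32500 UMIs gave a ratio of 1.15 (1.09–1.22). A transgene transcript whose 3′ end is not counted cannot be told apart from a transgene of low level, since the same ratio of 1.15 is what either would give and the construct's 3′ sequence is not given. A swap of the labels cannot be told apart either: the ratio of 1.05 (1.002–1.11) in cluster 1 lies between the 0.67 or less and the 1.5 or more that a counted transgene would give with swapped and with correct labels. A difference between the animals in transgene expression was not tested.

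Hepatocyte transcripts were higher in every other class of the library labelled Tg. Free RNA from 1 source would keep the 29 genes in 1 ratio between classes, and over 10 pairs of classes the median absolute deviation of their log2 ratios had a median of 0.0707 (0.0214–0.183), against 0.314 to 1.97 for other genes, which is consistent with that source. Doublets with a hepatocyte would leave most cells without these transcripts, but in lymphocyte-like cells of the library labelled Tg the 10th percentile of the list's share was 1.39% of UMIs, with a median of 2.42%, against 0.145% and 0.319% in that labelled WT. Whether more hepatocytes broke in the preparation or in the animal was not tested, and a genotype effect on hepatocyte fragility stays open.

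In monocyte-like cells the NF-kB list was lower in the library labelled Tg. Lymphocyte transcripts in the WT-labelled cells are argued against by a median of −0.58 (−0.83 to −0.36) without cells holding a T or NK cell marker. A stronger dissociation response in that preparation is argued against in finer cluster 23 of resolution 2.0 by an immediate early and dissociation list median of 0.041 (−0.11 to 0.59), but in the monocyte-like finer cluster, at −0.23 (−0.49 to 0.15), it cannot be told apart because the interval reaches past −0.4. A different mix of monocytes and dendritic cells is argued against in the monocyte-like finer cluster, where the median was −0.73 (−1.10 to −0.45), but in finer cluster 23, at −0.40 (−0.61 to −0.12), it cannot be told apart because the interval reaches past −0.2. A lower NF-kB activity in this mixed class of monocyte-like and dendritic cell-like cells was not measured. It is a hypothesis that these 2 libraries may raise but cannot separate from a difference between animals or preparations.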
